A study of Mus musculus with 15 samples.

How the data were processed

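RNA of cultured mouse mammary epithelial cells was hybridised to Affymetrix Mouse Gene arrays, 1 array per sample and 3 per group. Per the labels' protocols, Cre recombinase from an adenovirus deleted p53 or p53 and Rb, a retrovirus carried MYC, and RNA was amplified and labelled with a WT-Ovation Pico kit. The values are the intensity per probe set that the authors deposited, made with Affymetrix Expression Console 1.1, per the submitters' processing notes. The method of summarisation, the scale and any centring between arrays are not given in the sources used here. The deposited values had no negatives and ran from 4.11e-05 to 8348.1, so they were on a linear scale, and their median over all arrays was 47.32. Median intensities were 47.08, 46.81 and 41.28 in WT replicates 1 to 3, 53.5, 49.64 and 54.9 in p53-, 45.08, 45.63 and 43 in p53- Rb-, 46.54, 46.53 and 41.86 in p53- Myc+, and 48.71, 50.96 and 45.51 in p53- Rb- Myc+ arrays. The number of arrays limits the precision. The labels do not say whether the samples of a group came from separate animals or cultures, so p-values measure the spread between these samples, part of which may be technical. They also do not say whether the control cultures received a control virus, and they give no scan dates or batches. In the comparison of p53- Rb- Myc+ with p53- Myc+ arrays, same-number arrays deviated together from their group means (r = 0.102, 0.192 and 0.379, each p53- Myc+ array correlating best with the p53- Rb- Myc+ array of its own number), so the numbers were taken to pair these arrays. This pairing comes from the values and not from the labels, and held in none of the other 4 comparisons. It may be chance, since the own number correlated best in 12 of 30 same-number pairs of all groups.

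The groups, comparisons, tests, gene lists, rule for named genes and alternatives were chosen before the data were examined, except where a choice is said to be later. That plan took log2 values as its first case and, for linear values, log2 of the value plus 16, which was used here, with 1 and 64 added as alternatives. Of 35556 probe sets, 23410 were listed in the platform annotation used, 21789 with 1 gene symbol and 1621 with several; 12146 were not listed. Symbols of 21698 probe sets were checked through their Entrez gene numbers against a mouse gene table of assembly GRCm38.p6, used for names only, and 0 changed. Each of 19938 genes was represented by its probe set with the highest mean over the 15 arrays, which mattered for 999 genes with more than 1. Probe sets without a single gene name were not used in the comparisons.

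All 15 arrays entered 1 fit of group means with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 10 residual and 11.78 prior degrees of freedom, prior SD 0.2273, median residual SD 0.2301 on the log2 scale). A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison; tests were 2-sided. The 5 comparisons were p53- against WT, p53- Rb- against p53-, p53- Myc+ against p53-, p53- Rb- Myc+ against p53- Myc+, and p53- Rb- Myc+ against p53- Rb-, and the difference of both Rb comparisons was tested in the same fit. Changes are log2 fold changes ± SE, and rose and fell are used for passing genes. Comparisons with the same p53- arrays share their chance values. Intensities without an error are group means taken on the log2 scale and converted back.

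28 gene lists, 737 of whose 796 entries (92.59%) had a probe set, were tested with camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists, and again with an estimated correlation. They covered S-phase genes known as E2F targets, mitosis, p53 targets, ribosome biogenesis and metabolic genes known as MYC targets, glycolysis, cytosolic ribosomal proteins, luminal and basal epithelial genes, mesenchymal genes, proteases, integrins and adhesion, TGF-beta targets, Wnt targets, interferon-induced genes, inflammatory cytokines, hypoxia-induced genes, cholesterol synthesis, the unfolded protein response, DNA repair, the BCL2 family and caspases, CDK inhibitors with D cyclins and pocket proteins, milk protein genes, fibroblast, endothelial, leukocyte and adipocyte markers, and immediate early genes. Camera compares a list with all other genes, so a list can pass while few of its members do. List medians are given relative to the median of all genes. The mesenchymal list also holds genes that fibroblasts express, and no list shares more than 4 genes with others.

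The genes named were Rb1 and Myc in every comparison, the 8 with the highest and the 8 with the lowest fold change among passing genes at or above the median level whose 3 arrays in 1 group lay above the 3 of the other, and up to 4 members with the smallest p of each list described. For the 8 highest and lowest of the 5 comparisons of 2 groups, all 6 arrays therefore showed the direction. For the difference of both Rb comparisons, which rests on 12 arrays, no such rule on single arrays was applied.

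The alternatives were the mean of a gene's probe sets, all probe sets one by one, genes above the median level, centring each array, quantile normalization, the compared groups alone in the fit, a trended and robust variance prior, array weights, a replicate block, the other added constants, and leaving out each array in turn. Leaving out p53- array 2 and p53- Rb- array 3 together, and the added constants for the gene lists, were chosen after seeing the data. The steps were tested on simulated data: for p53 loss over 19938 genes with 200 changed, 7.46% of changes of 0.5 on the log2 scale were recovered, 61.2% of changes of 1 and 100% of changes of 2, with 6 calls among unchanged genes. In the simulated Rb comparison with the Myc+ label, made without any change, 0 genes and 0 lists were called. The simulated genes varied independently of each other, so this cannot show how often the list test calls lists of correlated genes. In the real data 29% of genes passed for p53 loss, a far larger share than was changed here. The adjusted threshold depends on that share, so the recovered percentages do not carry over directly.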

Results

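Transcript levels were measured on Affymetrix Mouse Gene arrays in cultured mammary epithelial cells of 8-week-old female mice. The 15 arrays fell into 5 groups of 3: wild type cells (WT), cells without p53 (p53-), cells without p53 and Rb (p53- Rb-), cells without p53 that were given a MYC retrovirus (p53- Myc+), and cells with all 3 changes (p53- Rb- Myc+). Each array gave 35556 probe set intensities, of which 21789 probe sets named 1 gene and represented 19938 genes. The median intensity of an array lay between 41.28 (WT replicate 3) and 54.9 (p53- replicate 3). Arrays of 1 group correlated across genes at r between 0.963 and 0.989, and arrays with different Myc labels at r between 0.776 and 0.865. In a principal component analysis, component 1 held 63.1% of the variance and set the 6 arrays labelled Myc+ (62.01 to 74.47) apart from the other arrays (-60.56 to -26.24).

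**Figure D1:**
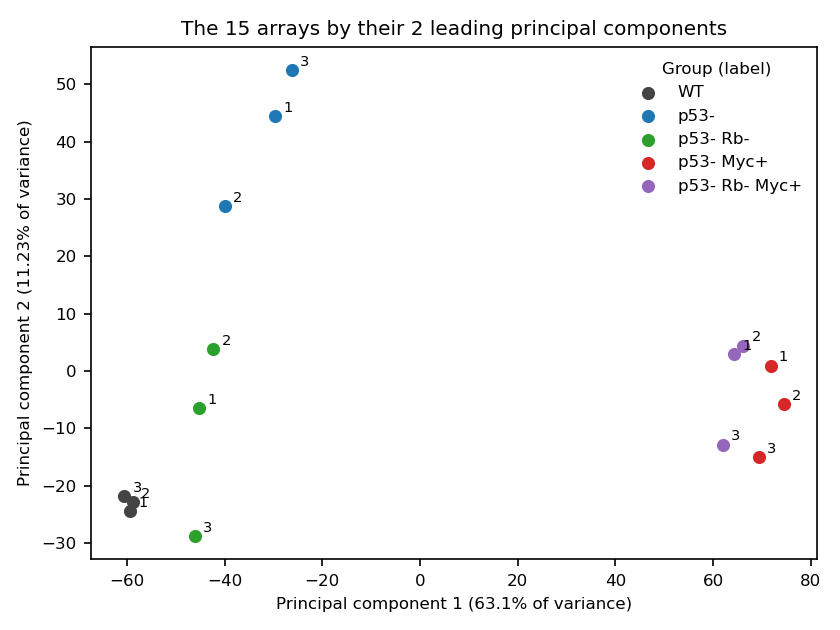
Principal components 1 and 2 of the log2 values of 19938 genes, with a point for each of the 15 arrays, coloured by group. The arrays labelled Myc+ lie at 62.01 to 74.47 on component 1 and all other arrays below 0.

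Rb1 encodes the retinoblastoma protein Rb, which restrains entry into S phase, and Myc encodes a transcription factor that drives growth. The Rb1 probe set (10421526) had a mean intensity of 92.79 ± 9.57 (SD, n = 3) in WT, 161.5 ± 17.3 in p53-, 57.39 ± 6.07 in p53- Rb-, 36.43 ± 10.8 in p53- Myc+ and 18.74 ± 1.09 in p53- Rb- Myc+ arrays. Rb1 thus fell with the Rb- label both without (log2 fold change -1.27 ± 0.16 (SE), adjusted p = 1.65e-05) and with the Myc+ label (-0.57 ± 0.16, adjusted p = 0.0452). The call with the Myc+ label ended in 14 of 26 alternatives, with adjusted p from 0.00548 to 0.24, the highest without p53- Myc+ replicate 1. With a replicate block, adjusted p was 0.0574. The block fitted the replicate numbers with effects shared by all 5 groups, so it did not model a pairing of this comparison alone. Rb1 was also lower in p53- Myc+ arrays, whose label leaves Rb intact, than in p53- arrays (-1.77 ± 0.16, adjusted p = 8.86e-09). Rb1 rose with p53 loss (0.71 ± 0.16, adjusted p = 0.00286) and fell with the Myc+ label among arrays labelled Rb- (-1.08 ± 0.16, adjusted p = 1.5e-05). Its changes with the Rb- label differed by 0.70 ± 0.23 (adjusted p = 0.0484), a call that ended in 19 of 26 alternatives, with adjusted p from 0.0042 to 0.254. The mouse Myc probe set (10424400) was lower, not higher, in the arrays labelled Myc+. Its mean intensity was 887.8 ± 47.9 in WT, 929.8 ± 105 in p53-, 855.7 ± 107 in p53- Rb-, 128.2 ± 29.5 in p53- Myc+ and 96.29 ± 10.8 in p53- Rb- Myc+ arrays. Myc fell by 2.73 ± 0.17 on the log2 scale from p53- to the arrays labelled p53- Myc+ (adjusted p = 9.47e-12) and by 2.95 ± 0.17 from p53- Rb- to p53- Rb- Myc+ (adjusted p = 2.31e-12). Myc did not pass with p53 loss (adjusted p = 0.817), with the Rb- label without (adjusted p = 0.656) or with the Myc+ label (adjusted p = 0.343), or in the difference of these (adjusted p = 0.565). These checks are limited, because the sources used here do not give which part of Rb1 or Myc the probes cover. Trp53, which encodes p53, was not analysed here, since no probe set named it alone.

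**Figure D2:**
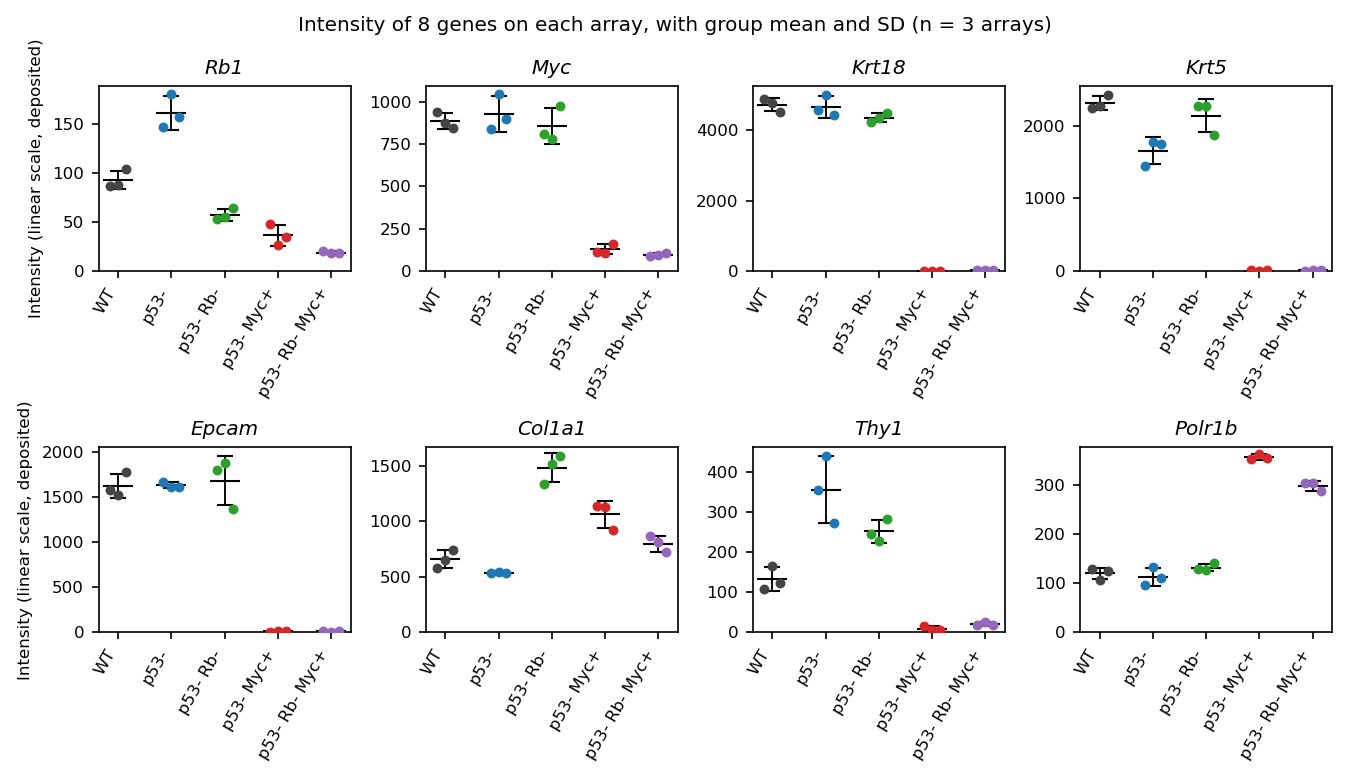
Intensities of 8 genes on each array (points, linear axis) with the mean and SD of each group of 3 arrays (lines), for WT, p53-, p53- Rb-, p53- Myc+ and p53- Rb- Myc+ arrays. The group means of Krt18, Krt5 and Epcam lie at 1627 or higher without and at 23.85 or lower with the Myc+ label, and Myc is lower in the arrays labelled Myc+.

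The comparison of p53- with WT cells asked what changed with the p53- label. Cre came from an adenovirus, and the labels do not say whether WT cultures received a control virus. An effect of that virus therefore cannot be told apart from one of p53 loss. Among genes that p53 is known to activate, Zmat3, which encodes an RNA-binding growth suppressor, changed by -1.81 ± 0.20 on the log2 scale (SE, 3 arrays per group, adjusted p = 2.18e-06). Dcxr, a xylulose reductase gene, changed by -2.19 ± 0.18 (adjusted p = 3.07e-08). The kinetochore genes Cenpe and Cenpf rose by 2.54 ± 0.27 (adjusted p = 1.27e-06) and 2.54 ± 0.28 (adjusted p = 1.87e-06). The acute-phase gene Saa1 fell from an intensity of 410.1 to 6.459 (log2 fold change -4.25 ± 0.17, adjusted p = 2.06e-13). The size of that change depends on the constant added before the logarithm, and was -5.81 with 1 added and -2.75 with 64 added. The luminal mucin gene Muc1 fell by 3.47 ± 0.19 (adjusted p = 7.21e-11), and the macrophage lysozyme gene Lyz2 fell by 3.17 ± 0.20 (adjusted p = 5.92e-10).

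Of 35 p53 targets, 16 fell, 2 rose and 17 did not pass; adjusted over the list alone, 17 fell and 4 rose. Their median lay -0.50 from that of all genes on the log2 scale (camera, adjusted p = 1.54e-07), and Psrc1 (-1.74) and Ak1 (-1.78) were further examples. Among 38 mitosis genes, 33 rose and 5 did not pass (adjusted over the list alone, 34 rose), with a median 0.71 above all genes (adjusted p = 6.64e-16), including Bub1 (1.75) and Ttk (1.57). Of 46 S-phase genes known as E2F targets, 24 rose and 22 did not pass (30 rose adjusted over the list alone, adjusted p = 4.66e-06), with Hells at 2.03 and Ccne2 at 1.85. DNA repair genes rose in 19 of 25 (also 19 adjusted over the list alone, adjusted p = 2.81e-07), among them Chek1 (1.70) and Brca1 (1.24). These 4 lists kept their calls in camera with an estimated correlation, by a narrower margin. Adjusted p was then 0.0187 for p53 targets and 0.0419 each for mitosis, E2F target and DNA repair genes. The lists of inflammatory (0.0425), leukocyte (0.0328) and endothelial genes (0.0419) kept theirs too. Inflammatory cytokine genes fell in 13 of 28 and rose in 3 (14 and 4 adjusted over the list alone, adjusted p = 1.64e-05), including Saa3 (-2.70) and Tnf (-1.64), while Tslp rose by 2.29. Leukocyte markers fell beside them in 8 of 23 and rose in 1 (the same counts adjusted over the list alone, adjusted p = 0.000114), including Cd14 (-2.21). Endothelial markers fell in 6 of 19 and rose in 2 (the same counts adjusted over the list alone, adjusted p = 0.00606). Whether WT and p53- cultures differed in their mix of cells was not tested.

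Luminal epithelial genes fell in 13 of 38 (also 13 adjusted over the list alone, adjusted p = 1.29e-06 and adjusted p = 0.0529 with an estimated correlation), including Ltf (-2.70) and Kit (-1.99). Interferon-induced genes rose in 16 of 33 (17 adjusted over the list alone, adjusted p = 0.000652 and adjusted p = 0.293 with an estimated correlation), with Cxcl10 at 1.42 and Rsad2 at 1.14. Ribosome biogenesis genes known as MYC targets rose in 20 of 41 and fell in 1 (23 and 1 adjusted over the list alone, adjusted p = 0.000114 and adjusted p = 0.14 with an estimated correlation), with Nop58 at 1.44 and Gnl3 at 1.32. Metabolic MYC targets rose in 13 of 35 (also 13 adjusted over the list alone, adjusted p = 0.0289 and adjusted p = 0.293 with an estimated correlation), Mthfd2 by 1.56 and Hspd1 by 0.99. Fibroblast markers fell in 8 of 20 and rose in 2 (the same counts adjusted over the list alone, adjusted p = 0.00021 and adjusted p = 0.163 with an estimated correlation): Col6a3 fell by 1.52, and Thy1 rose by 1.31. Basal genes fell in 4 of 27 and rose in 1 (3 and 1 adjusted over the list alone, adjusted p = 0.0289 and adjusted p = 0.293 with an estimated correlation). The adhesion gene Dst rose by 1.24. Glycolysis (adjusted p = 0.00448 and adjusted p = 0.111 with an estimated correlation), cholesterol synthesis (0.00448 and 0.22) and immediate early genes (0.00799 and 0.302) moved down as lists. Of these, 4 of 18, 4 of 20 and 4 of 21 fell and 0, 1 and 2 rose (adjusted over the list alone, 4, 6 and 5 fell and 0, 1 and 2 rose). The other 12 lists did not pass, from targets of TGF-beta (adjusted p = 0.0707) to cytosolic ribosomal proteins (adjusted p = 0.909). Among these, mesenchymal genes rose in 9 of 33 and fell in 7, with Cdh2 among the risers and Fstl1 at -1.25. Proteases rose in 4 of 31 and fell in 8, with Adamts1 at 1.36 and Mmp2 at -1.02. The test was positive and the median below all genes for cytosolic ribosomal proteins, and the reverse held for Wnt targets.

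In total 5777 genes passed limma's moderated test: 3842 rose and 1935 fell, and 811 and 325 of these changed at least 2-fold. Without adjustment, 8022 genes passed, and for 8023 genes (40.2%, against 10% by chance) the 3 arrays of 1 group lay above the 3 of the other. Risers were 66.5% of the calls, but 41.6% after centring each array and 47.3% after quantile normalization, and the median change of all genes moved from 0.12 to -0.05 with centring. Without p53- replicate 3, 3467 genes passed. Apart from the estimated correlation, alternatives ended the calls of metabolic MYC targets (5 of 26, adjusted p from 0.00145 to 0.142), basal genes (6 of 26, 0.00686 to 0.176), interferon-induced genes (1 of 26, 0.000109 to 0.665) and immediate early genes (1 of 26, 0.00224 to 0.067). Among these, metabolic MYC targets lost the call without WT replicate 2 (adjusted p = 0.0699) or p53- replicate 2 (0.142), and basal genes without WT replicate 3 (0.0994), p53- replicate 1 (0.0645) or p53- replicate 3 (0.0545).

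p53- Rb- cells were set against p53- cells to ask what Rb loss added in the absence of p53. The collagen gene Col1a1 rose from a mean intensity of 538.6 ± 5.29 to 1479 ± 130 (SD, n = 3), a log2 fold change of 1.43 ± 0.16 (SE, adjusted p = 2.83e-06), and Col3a1 rose by 1.39 ± 0.16 (adjusted p = 4.28e-06). The microfibril genes Mfap4 (3.10 ± 0.24, adjusted p = 2.66e-08) and Mfap5 (2.51 ± 0.22, adjusted p = 1.39e-07) rose with them. Muc1 rose by 3.89 ± 0.19 (adjusted p = 1.93e-11), from an intensity of 18.56 to 496.4. Car9, a carbonic anhydrase gene induced by hypoxia, rose by 2.08 ± 0.17 (adjusted p = 8.25e-08). The nuclear receptor gene Nr1h5 fell by 2.95 ± 0.18 (adjusted p = 1.08e-09) and the ubiquitin ligase gene Mid1 fell by 2.76 ± 0.45 (adjusted p = 0.000185). A change here need not be a departure from WT: Muc1 had fallen with p53 loss, and Nr1h5 lay higher in p53- arrays than in each other group.

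Mesenchymal genes rose in 21 of 33 and fell in 1 (adjusted over the list alone, 25 and 1), with a median 0.85 above all genes (camera, adjusted p = 5.2e-15 and adjusted p = 0.0549 with an estimated correlation), including Thbs2 (1.37) and Itga5 (1.40). Fibroblast markers moved with them, as 13 of 20 rose (15 rose and 1 fell adjusted over the list alone, median 1.05 above all genes, adjusted p = 1.11e-11), with Col15a1 at 2.19 and Col6a1 at 1.85. Hypoxia-induced genes rose in 12 of 21 (12 rose and 1 fell adjusted over the list alone, adjusted p = 2.98e-08), P4ha2 by 1.31 and Bnip3 by 1.13. Glycolysis genes rose in 11 of 18 (also 11 adjusted over the list alone, adjusted p = 4.92e-08), Aldoc by 1.84 and Eno2 by 1.48. The fibroblast, hypoxia and glycolysis lists kept their calls in camera with an estimated correlation (adjusted p = 0.0355, 0.0355 and 0.0317). Proteases rose in 11 of 31 and fell in 2 (12 and 3 adjusted over the list alone, adjusted p = 0.00471 and adjusted p = 0.252 with an estimated correlation), with Mmp2 at 1.37 and Serpinb2 at -1.07.

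E2F targets, which Rb is known to repress, rose in 10 of 46 and fell in 4 (adjusted over the list alone, 13 and 5), with a median 0.32 above all genes (adjusted p = 0.0244 and adjusted p = 0.334 with an estimated correlation). Cdkn2c rose by 0.72 ± 0.17 (adjusted p = 0.00375), while Hells (-1.90) and Ccne2 (-1.26) fell. Mitosis genes did not pass as a list (adjusted p = 0.805), and 5 of 38 rose while 8 fell, including Cenpe (-1.78) and Bub1 (-1.16). Interferon-induced genes fell in 13 of 33 and rose in 2 (15 and 2 adjusted over the list alone, adjusted p = 0.0223 and adjusted p = 0.43 with an estimated correlation), including Cxcl10 (-1.92) and Rsad2 (-1.38). Among the genes of the metabolic MYC list, 7 of 35 rose and 4 fell (the same counts adjusted over the list alone, adjusted p = 0.0253 and adjusted p = 0.338 with an estimated correlation), with Got1 at 0.66 and Odc1 at -0.72. Cholesterol synthesis (adjusted p = 0.0118 and adjusted p = 0.334 with an estimated correlation) and immediate early genes (0.0253 and 0.43) moved up as lists. Luminal genes (adjusted p = 0.0526, Elf5 at 1.18), basal genes (adjusted p = 0.137, Cnn1 at 1.36), p53 targets (adjusted p = 0.221, Ak1 at 2.02) and inflammatory genes (adjusted p = 0.142) did not pass. The ribosome biogenesis list did not pass either (adjusted p = 0.726). Its median lay above all genes and its test pointed down, and Nop58 fell by 1.24. Hells, Ccne2, Cenpe, Bub1, Cxcl10, Rsad2 and Nop58, which fell here, had risen with p53 loss, and Ak1 had fallen with it.

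With Rb loss in these cells 3949 genes passed limma's test, of which 1866 rose and 2083 fell (330 and 439 at least 2-fold), and 6656 passed without adjustment. Of the genes that fell, 1567 had risen with p53 loss, and both comparisons share the p53- arrays. For 7972 genes (40%, against 10% by chance) the arrays of the groups did not overlap. Risers made up 47.3% of the calls, 74.9% after centring and 59.1% after quantile normalization, and the median change of all genes moved from -0.08 to 0.10 with centring. The count was 2478 without p53- replicate 1, 2128 without p53- replicate 3, 2096 without p53- Rb- replicate 3 and 8515 with array weights. Alternatives other than the estimated correlation ended the calls of E2F targets (4 of 26, adjusted p from 0.00951 to 0.414), metabolic MYC targets (3 of 26, 0.00944 to 0.363), proteases (2 of 26, 0.00159 to 0.414), interferon-induced genes (6 of 26, 0.00147 to 0.388), cholesterol synthesis (2 of 26, 0.00253 to 0.246) and immediate early genes (5 of 26, 0.00684 to 0.266). Single arrays did so for E2F targets (without p53- replicate 1, adjusted p = 0.0751, or p53- Rb- replicate 2, 0.0569), metabolic MYC targets (p53- replicate 1, 0.0726), interferon-induced genes (p53- replicate 2, 0.0639, or p53- Rb- replicate 3, 0.159) and immediate early genes (p53- replicate 1, 0.0702, p53- replicate 3, 0.0513, or p53- Rb- replicate 3, 0.0533). Among genes above the median level, the median of the interferon-induced list reversed to 0.217 (adjusted p = 0.363). The call of Cdkn2c ended without p53- array 2 and p53- Rb- array 3 together, a choice made after seeing the data (adjusted p = 0.057, and 0.000746 to 0.057 over 27 alternatives).

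The p53- Myc+ arrays were compared with p53- arrays to ask what changed with the Myc+ label in cells without the Rb- label. Directions rest on the labels, and the mouse Myc probe set, which may not read the transgene, was lower with the Myc+ label. Neither group carries the Rb- label, but Rb1 was lower in p53- Myc+ (36.43) than in p53- (161.5) and also than in p53- Rb- arrays (57.39), so whether Rb was present at an ordinary level is open. The epithelial transcripts Krt18, Krt5 and Epcam fell to near the bottom of the scale. Krt18 of luminal cells had a mean intensity of 4669 ± 305 (SD, n = 3) in p53- and 4.78 ± 5.3 in p53- Myc+ arrays, and Krt5 of basal cells fell from 1656 ± 184 to 5.513 ± 4.84. Epcam, an epithelial adhesion gene, fell from 1634 ± 32.5 to 10.26 ± 4.13. Polr1b, which encodes an RNA polymerase I subunit, rose from 112.8 ± 18 to 355.6 ± 5.44 (log2 fold change 1.54 ± 0.15 (SE), adjusted p = 2e-08). The secreted Wnt modulator gene Sfrp2 rose by 4.34 ± 0.20 (adjusted p = 6.43e-14), and the adhesion gene Vcam1 by 3.58 ± 0.21 (adjusted p = 2.6e-12).

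Luminal epithelial genes fell in 35 of 38 (adjusted over the list alone, 36), with a median -3.31 from all genes (camera, adjusted p = 3.75e-34), including Krt18 (-7.84 ± 0.17, adjusted p = 4.1e-19) and Krt7 (-6.82 ± 0.15, adjusted p = 7.24e-19). Basal genes fell in 21 of 27 and rose in 2 (22 and 2 adjusted over the list alone, adjusted p = 4.91e-17), including Krt5 (-6.30 ± 0.18) and Krt14 (-6.15). Among ribosome biogenesis genes, 34 of 41 rose (37 adjusted over the list alone, median 1.00 above all genes, adjusted p = 6.21e-19), with Polr1e at 1.44. Metabolic MYC targets rose in 27 of 35 and fell in 1 (31 and 1 adjusted over the list alone, adjusted p = 7.29e-15), Srm by 1.78 and Cad by 1.73. E2F targets rose in 31 of 46 and fell in 1 (31 and 2 adjusted over the list alone, adjusted p = 3.05e-10), Pola2 by 1.03. The list of p53 targets moved down (adjusted p = 0.000208), as 20 of 35 fell and 3 rose (adjusted over the list alone, 20 and 4), among them Perp (-5.09) and Plk2 (-2.56). Both groups carry the p53- label, so p53 loss does not set them apart. In p53- against WT arrays, Perp (-0.04, limma, adjusted p = 0.868) and Plk2 (0.40, adjusted p = 0.0535) did not pass. Interferon-induced genes fell in 31 of 33 (also 31 adjusted over the list alone, adjusted p = 5.32e-15), including Rtp4 (-3.83). Targets of TGF-beta fell in 18 of 23 and rose in 3 (20 and 3 adjusted over the list alone, adjusted p = 1.35e-09), including Inhba (-4.39). Integrin and adhesion genes fell in 18 of 25 (also 18 adjusted over the list alone, adjusted p = 2.51e-09), including Cd44 (-5.67). Proteases fell in 19 of 31 and rose in 4 (20 and 4 adjusted over the list alone, adjusted p = 1.83e-07), including Serpinb5 (-4.89) and Timp3 (-5.85). These 10 lists kept their calls in camera with an estimated correlation. Adjusted p then ran from 0.00104 for luminal genes to 0.0273 for integrin and adhesion genes.

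Mesenchymal genes rose in 16 of 33 and fell in 6 (the same counts adjusted over the list alone, adjusted p = 0.000314 and adjusted p = 0.26 with an estimated correlation), with Twist2 at 2.58 and Tnc at -2.93. Fibroblast markers divided beside them: 9 of 20 rose and 6 fell (the same counts adjusted over the list alone, adjusted p = 0.0293 and adjusted p = 0.315 with an estimated correlation), with Dpt at 3.32 ± 0.20, Pdgfra at 2.49 and Thy1 at -3.86. Mitosis genes rose in 13 of 38 and fell in 3 (14 and 3 adjusted over the list alone, adjusted p = 0.000401 and adjusted p = 0.26 with an estimated correlation), Bub1b by 1.26. Cholesterol synthesis genes rose in 9 of 20 (11 rose and 1 fell adjusted over the list alone, adjusted p = 0.000192 and adjusted p = 0.085 with an estimated correlation), Mvk by 1.47. DNA repair genes moved up as a list (adjusted p = 0.000257 and adjusted p = 0.0826 with an estimated correlation). Inflammatory genes (adjusted p = 0.000192 and adjusted p = 0.0593 with an estimated correlation), immediate early genes (0.00112 and 0.227), unfolded protein response genes (0.0152 and 0.265), BCL2 family genes and caspases (0.0338 and 0.107) and endothelial markers (0.0472 and 0.0876) moved down. Leukocyte markers did not pass (adjusted p = 0.51), nor did markers of adipocytes (adjusted p = 0.751), milk protein genes (adjusted p = 0.114), glycolysis (adjusted p = 0.0819) or hypoxia-induced genes (adjusted p = 0.648). For the Wnt (adjusted p = 0.629) and adipocyte lists the median lay below all genes and the test pointed up.

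Between these groups 6640 genes passed, 2606 of which rose and 4034 fell (660 and 1830 at least 2-fold), and 8194 passed without adjustment. For 8493 genes (42.6%, against 10% by chance) the arrays did not overlap. Risers were 39.2% of the calls, 56.3% after centring and 51.5% after quantile normalization, and the median change of all genes moved from -0.09 to 0.08 with centring. The low intensities make the size of the keratin changes depend on the constant added before the logarithm: the log2 fold change of Krt18 was -10.13 with 1 added and -6.11 with 64 added. Other alternatives ended the calls of the BCL2 and caspase list (3 of 26, adjusted p from 0.0223 to 0.0825), fibroblast markers (3 of 26, 0.0192 to 0.0852) and endothelial markers (11 of 26, 0.0368 to 0.548). Among these, the BCL2 and caspase list lost the call without p53- replicate 2 (adjusted p = 0.0537) or p53- Myc+ replicate 1 (0.0825). Endothelial markers lost it without WT replicate 2 (0.0501), p53- replicate 1 (0.0671), p53- replicate 2 (0.0539), p53- Myc+ replicate 2 (0.0583) or p53- Rb- Myc+ replicate 3 (0.0505).

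Comparing p53- Rb- Myc+ with p53- Myc+ arrays addressed what the Rb- label added to the Myc+ label, the setting in which the series' title places invasion. Differences here are by label only, because Rb1 was already at 36.43 in the p53- Myc+ arrays. Efemp1, a fibulin gene of the extracellular matrix, rose by 5.44 ± 0.20 on the log2 scale (SE, 3 arrays per group, adjusted p = 4.68e-14), from an intensity of 7.707 to 1010. The complement inhibitor gene Serping1 rose by 4.39 ± 0.18 (adjusted p = 1.79e-13) and the IGF-binding protein gene Igfbp4 by 3.96 ± 0.19 (adjusted p = 2.82e-12). Slc43a3, which encodes a purine transporter, fell by 4.30 ± 0.16 (adjusted p = 4.68e-14), and the matrix protease gene Mmp3 fell by 2.97 ± 0.18 (adjusted p = 8.17e-11).

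No list kept its call with an estimated correlation here (lowest adjusted p = 0.417), and 8 of 28 passed camera with its preset correlation. Luminal genes moved up as a list (adjusted p = 2.16e-05): 5 of 38 rose (adjusted over the list alone, 7), among them Krt19 (2.47), Lcn2 (2.45) and Cd24a (2.25). They stayed far below WT, as 36 of 38 were lower in p53- Rb- Myc+ than in WT arrays (median log2 fold change -3.53). Epcam lay at mean intensities of 10.26 in p53- Myc+ and 11.57 in p53- Rb- Myc+ arrays. Mesenchymal genes moved down (adjusted p = 2.16e-05), and 6 of 33 fell and 1 rose (adjusted over the list alone, 6 and 3), including Tnc (-2.09), Thbs2 (-2.06) and Postn (-2.06). Fibroblast markers moved down beside them (adjusted p = 0.00382), with 6 of 20 falling and 2 rising (adjusted over the list alone, 6 and 3), including Dpt (-1.63) and Pdgfra (-1.40). Targets of TGF-beta fell in 6 of 23 and rose in 3 (8 and 4 adjusted over the list alone, adjusted p = 0.00807), with Igfbp3 at -1.81 and Id1 at 1.66. Interferon-induced genes rose in 4 of 33 (8 adjusted over the list alone, adjusted p = 0.00382), Isg20 by 1.08 and Stat2 by 0.98. Wnt targets fell in 4 of 19 (also 4 adjusted over the list alone, adjusted p = 0.0179). The ribosome biogenesis list moved down (adjusted p = 0.00304) with 0 of 41 members passing, Polr1e at -0.39 (adjusted p = 0.178). The metabolic MYC list moved down (adjusted p = 0.0375) with 1 of 35 falling, which was Ccnd2 (-0.79). E2F targets did not pass (adjusted p = 0.418), and 1 of 46 rose (also 1 adjusted over the list alone), Cdkn2c by 1.21 ± 0.17 (adjusted p = 2.67e-05). Mitosis genes did not pass (adjusted p = 0.967), nor did proteases (adjusted p = 0.357), basal genes (adjusted p = 0.81), of which Pdpn rose by 2.33, or p53 targets (adjusted p = 0.858), of which Sesn1 rose by 1.21. The median and the test differed in sign for the p53 target and unfolded protein response lists.

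Between the arrays labelled p53- Rb- Myc+ and p53- Myc+, 935 genes differed: 656 rose and 279 fell, 245 and 97 at least 2-fold, and 2968 genes passed without adjustment. For 4087 genes (20.5%, against 10% by chance) the arrays did not overlap, and risers were 70.2% of the calls, 57.1% after centring and 60.4% after quantile normalization. Alternatives other than the estimated correlation ended the calls of metabolic MYC targets (6 of 26, adjusted p from 0.0106 to 0.193), TGF-beta targets (2 of 26, 0.00138 to 0.112) and Wnt targets (1 of 26, 0.00304 to 0.0606). Metabolic MYC targets lost the call without p53- Myc+ replicate 3 (adjusted p = 0.159), p53- Rb- Myc+ replicate 2 (0.0585) or p53- Rb- Myc+ replicate 3 (0.071), TGF-beta targets without p53- Myc+ replicate 3 (0.0642) and Wnt targets without p53- Myc+ replicate 2. The replicate numbers were taken to pair the arrays of this comparison by their values, but the replicate block is shared by all 5 groups. With that block the cholesterol synthesis list moved up (adjusted p = 0.0475, against 0.0521 without the block and 0.488 with the block and an estimated correlation).

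The arrays labelled p53- Rb- Myc+ were compared with p53- Rb- arrays to ask what changed with the Myc+ label in cells with the Rb- label, with directions again drawn from the labels. Krt18 fell from a mean intensity of 4362 ± 127 to 23.85 ± 2.51 (SD, n = 3), a log2 fold change of -6.78 ± 0.17 (SE, adjusted p = 5.59e-18). Krt5 fell from 2138 ± 228 to 9.904 ± 3.87, and Epcam fell from 1682 ± 273 to 11.57 ± 2.57. Polr1b rose from 131.4 ± 7.47 to 296.9 ± 9.24. The interferon-inducible membrane protein gene Ifitm1 rose by 4.39 ± 0.19 (adjusted p = 2.55e-14), the lubricin gene Prg4 by 4.33 ± 0.19 (adjusted p = 2.31e-14), and Ogn, a small proteoglycan gene of connective tissue, by 3.46 ± 0.21 (adjusted p = 9.71e-12).

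Luminal genes fell in 35 of 38 (also 35 adjusted over the list alone, median -3.05 from all genes, camera, adjusted p = 5.06e-36), including Cldn4 (-6.06). Basal genes fell in 21 of 27 and rose in 2 (the same counts adjusted over the list alone, adjusted p = 7.92e-19), including Krt14 (-5.85). Ribosome biogenesis genes rose in 37 of 41 (40 adjusted over the list alone, median 0.79 above all genes, adjusted p = 7.89e-14), Npm1 by 1.32 and Heatr1 by 1.20. Metabolic MYC targets rose in 20 of 35 and fell in 1 (the same counts adjusted over the list alone, adjusted p = 6.95e-07), Srm by 1.45. The p53 targets fell in 22 of 35 and rose in 3 (24 and 3 adjusted over the list alone, adjusted p = 3.94e-07), including Ak1 (-4.32), although both groups carry the p53- label. Proteases fell in 23 of 31 and rose in 3 (24 and 3 adjusted over the list alone, adjusted p = 1.11e-14), including Mmp9 (-5.44) and Mmp3 (-4.33). Of the TGF-beta targets, 18 of 23 fell and 1 rose (20 and 1 adjusted over the list alone, adjusted p = 6.83e-14), including Pmepa1 (-4.39). Of the integrin list, 22 of 25 fell (22 fell and 1 rose adjusted over the list alone, adjusted p = 4.21e-12), including Cd44 (-4.54). Endothelial markers fell in 9 of 19 and rose in 1 (the same counts adjusted over the list alone, adjusted p = 0.00218). These 9 lists kept their calls with an estimated correlation.

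Calls that ended with an estimated correlation included E2F targets (20 of 46 rose, also 20 adjusted over the list alone, adjusted p = 4.4e-05 and adjusted p = 0.051 with an estimated correlation), with Ccne2 at 1.76 and Hells at 1.72. Mitosis genes rose in 18 of 38 (also 18 adjusted over the list alone, adjusted p = 0.00166 and adjusted p = 0.282 with an estimated correlation), Kif11 by 1.17. Mesenchymal genes fell in 17 of 33 and rose in 9 (the same counts adjusted over the list alone, adjusted p = 0.00246 and adjusted p = 0.296 with an estimated correlation), including Tnc (-5.43) and Fn1 (-2.94). Fibroblast markers fell with them in 11 of 20 and rose in 3 (the same counts adjusted over the list alone, adjusted p = 0.0017 and adjusted p = 0.178 with an estimated correlation), with Mfap5 at -4.19 and Mgp at -3.12. Interferon-induced genes fell in 21 of 33 and rose in 1 (the same counts adjusted over the list alone, adjusted p = 2.93e-07 and adjusted p = 0.106 with an estimated correlation), including Zbp1 (-3.06). DNA repair (adjusted p = 5.29e-05 and adjusted p = 0.0542 with an estimated correlation) and cholesterol synthesis genes (0.00656 and 0.178) moved up. Immediate early (adjusted p = 5.24e-07 and adjusted p = 0.0642 with an estimated correlation), inflammatory (0.000125 and 0.0542), unfolded protein response (0.000216 and 0.117) and hypoxia-induced genes (0.00784 and 0.178) moved down. CDK inhibitor and pocket protein genes did not pass (adjusted p = 0.851). Their median and test differed in sign, as they did for cytosolic ribosomal proteins (adjusted p = 0.708).

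Here 7246 genes passed, of which 3518 rose and 3728 fell (662 and 1888 at least 2-fold), and 8966 passed without adjustment. For 10212 genes (51.2%, against 10% by chance) the arrays did not overlap. Risers were 48.6% of the calls, 38.8% after centring and 45.5% after quantile normalization, and the median change of all genes moved from 0.12 to 0.04 with centring. The log2 fold change of Krt18 was -7.46 with 1 added before the logarithm and -5.66 with 64 added. Restricting the test to genes above the median level ended the calls of mesenchymal genes (adjusted p = 0.0538, and 0.000551 to 0.0538 over 26 alternatives), hypoxia-induced genes (0.169, and 0.00352 to 0.169) and endothelial markers (0.13, and 0.00144 to 0.13).

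**Figure D3:**
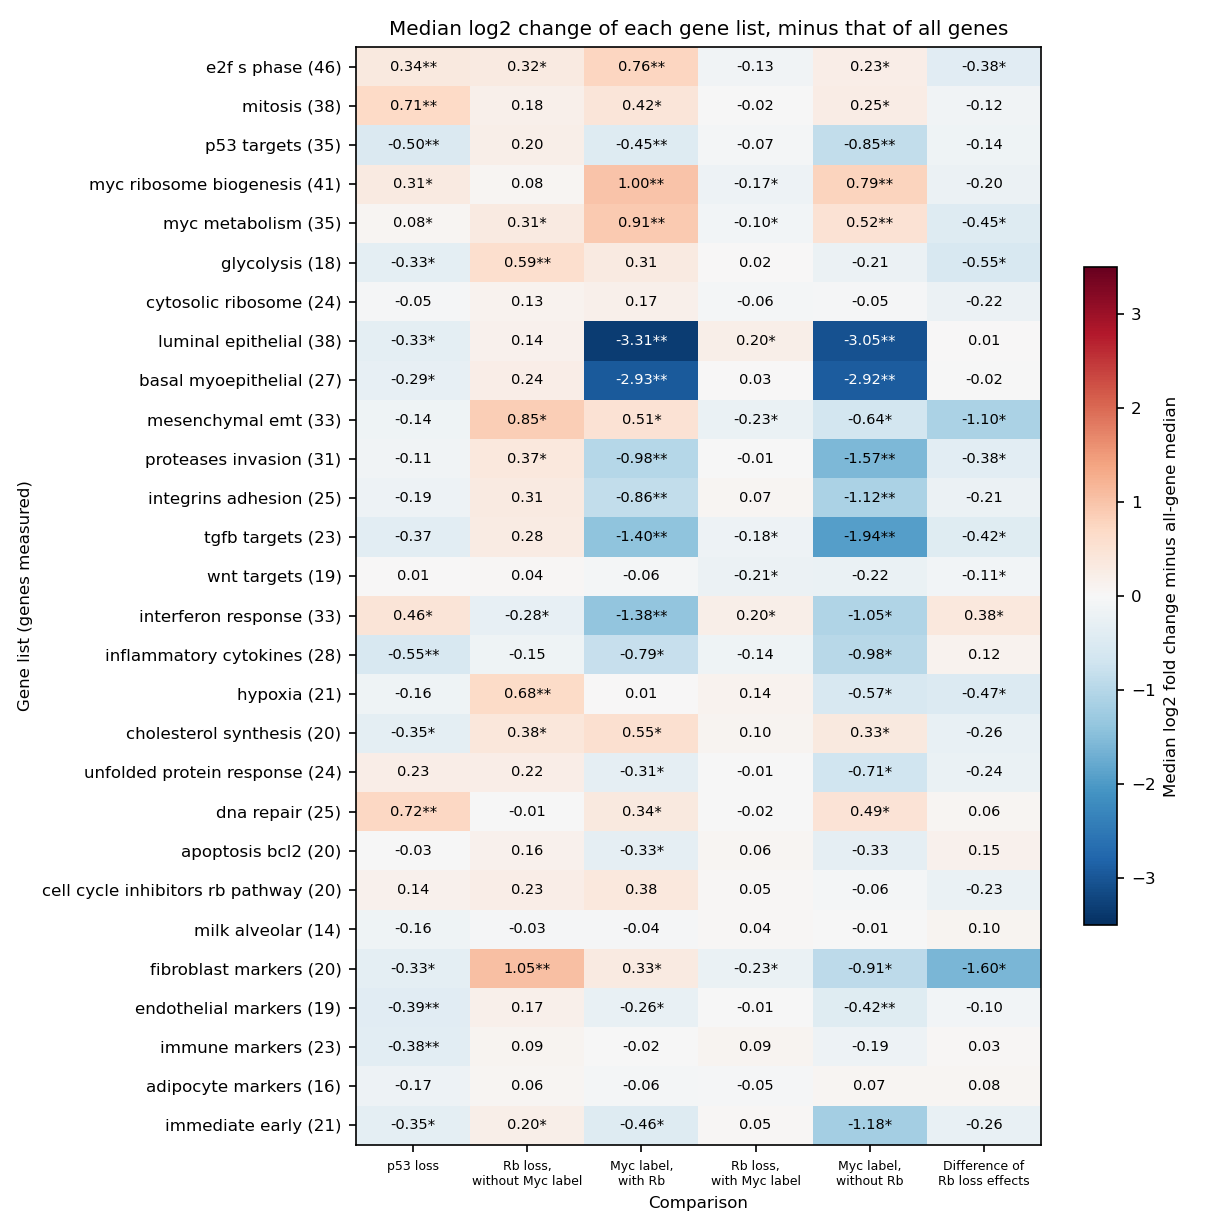
Median log2 fold change of each of the 28 gene lists minus that of all genes (colour and number) in the 6 comparisons, with the number of genes measured beside each list. A single asterisk marks a call with camera's preset correlation and a double one a call that also held with an estimated correlation, and luminal genes lie at -3.31 and -3.05 with the Myc+ label.

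Whether the change with the Rb- label differed between cells without and with the Myc+ label was tested as the difference of both changes. The change in Efemp1 was higher with the Myc+ label by 5.28 ± 0.29 on the log2 scale (SE, 3 arrays in each of 4 groups, adjusted p = 1.05e-10), and that in Igfbp4 by 3.89 ± 0.27 (adjusted p = 2.32e-09). The changes in Mfap4 (-5.72 ± 0.33, adjusted p = 2.57e-10), Slc43a3 (-5.30 ± 0.23, adjusted p = 1.66e-12) and the angiogenesis inhibitor gene Thbs2 (-3.43 ± 0.22, adjusted p = 1.15e-09) were lower. Muc1, which rose with the Rb- label in cells without the Myc+ label, differed by -3.79 ± 0.27 (adjusted p = 3.3e-09), and it lay near the bottom of the scale in both groups labelled Myc+ (intensities of 8.546 and 10.22).

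Mesenchymal genes showed the difference in 20 of 33, all lower with the Myc+ label (22 adjusted over the list alone, median -1.10 from all genes, camera, adjusted p = 1.03e-18 and adjusted p = 0.0519 with an estimated correlation), Tnc by -2.50 and Postn by -2.60. Of 20 fibroblast markers, 13 were lower and 3 higher (14 and 3 adjusted over the list alone, median -1.60, adjusted p = 2.94e-12 and adjusted p = 0.0519 with an estimated correlation), among them Col6a3 (-2.90) and Dpt (-2.56). Glycolysis genes differed in 5 of 18, all lower (6 adjusted over the list alone, adjusted p = 4.34e-05 and adjusted p = 0.0519 with an estimated correlation), Aldoc by -1.38. Hypoxia-induced genes differed in 9 of 21, all lower (10 lower and 1 higher adjusted over the list alone, adjusted p = 3.93e-05 and adjusted p = 0.0941 with an estimated correlation), Car9 by -1.94. Proteases were lower in 8 of 31 and higher in 4 (11 and 8 adjusted over the list alone, adjusted p = 0.0024 and adjusted p = 0.177 with an estimated correlation), with Mmp3 at -3.16 and Mmp2 at -2.63. Interferon-induced genes were higher in 14 of 33 (also 14 adjusted over the list alone, adjusted p = 0.000146 and adjusted p = 0.328 with an estimated correlation), Cxcl10 by 2.00 and Rsad2 by 1.47. E2F targets were higher in 3 of 46 and lower in 1 (adjusted over the list alone, the same counts), with a median -0.38 from all genes (adjusted p = 0.0197 and adjusted p = 0.328 with an estimated correlation), and Hells (1.81) and Ccne2 (1.43) went against it. Lists of metabolic MYC targets (adjusted p = 0.0024 and adjusted p = 0.177 with an estimated correlation), Wnt targets (0.00706 and 0.121) and TGF-beta targets (0.00636 and 0.345) were lower too. Luminal genes (adjusted p = 0.475, Krt19 at 2.48), basal genes (adjusted p = 0.656, Itga6 at 1.86), mitosis genes (adjusted p = 0.847, Cenpe at 2.14), p53 targets (adjusted p = 0.531, Pmaip1 at 1.55) and ribosome biogenesis genes (adjusted p = 0.223, Nop58 at 1.17) did not pass as lists. For the leukocyte and adipocyte lists the median lay above all genes and the test pointed down.

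The difference passed for 2715 genes, in 1749 of which the change was higher with the Myc+ label and in 966 lower, and for 5611 without adjustment. Higher changes were 64.4% of the calls, 28.8% after centring and 46.7% after quantile normalization, and the median difference of all genes moved from 0.13 to -0.13 with centring. The count was 1760 without p53- replicate 3, 1793 without p53- Rb- Myc+ replicate 2 and 5397 with array weights. Alternatives other than the estimated correlation ended the calls of E2F targets (3 of 26, adjusted p from 0.00787 to 0.431), metabolic MYC targets (2 of 26, 0.000835 to 0.143), proteases (2 of 26, 0.000881 to 0.256), TGF-beta targets (2 of 26, 0.0012 to 0.292) and interferon-induced genes (1 of 26, 6.55e-06 to 0.195). Without p53- replicate 1, E2F targets lost the call (adjusted p = 0.0599).

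**Figure D4:**
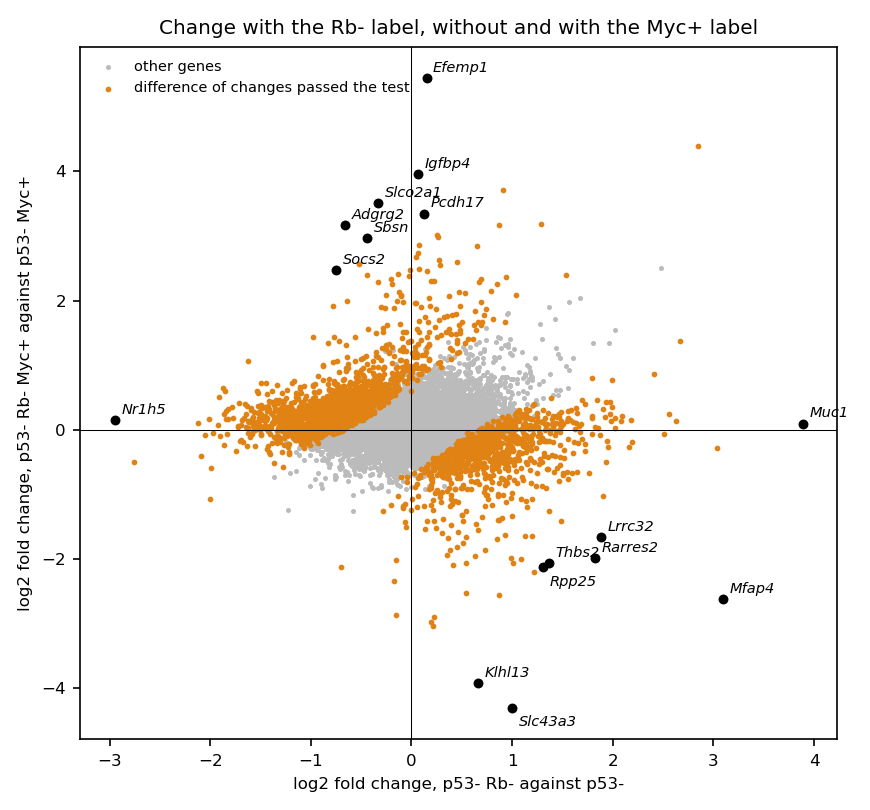
Log2 fold change of each of 19938 genes with the Rb- label, without (horizontal axis) and with (vertical axis) the Myc+ label. Colour marks the 2715 genes whose changes differed, and Efemp1 lies at 5.44 on the vertical axis and Muc1 at 3.89 on the horizontal axis.

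Across genes, which are not independent replicates, the changes with the Rb- label without and with the Myc+ label, which share no arrays, were not correlated (Pearson r = -0.0218, Spearman rho = -0.0603). Genes such as Serping1, which rose in both by 2.84 and 4.39, numbered 181, against 61.4 for independent lists. A further 25 genes fell in both, against 29.15, and 147 went opposite ways, against 94.65, among them Mfap4 and Thbs2. The changes with the Myc+ label, without and with the Rb- label, which share no arrays either, correlated at r = 0.751 (rho = 0.528). In these, 1326 genes rose in both (459.8 for independent lists), such as Aldh1a1 by 3.44 and 3.62, and 2578 fell in both (754.3 for independent lists), such as Krt18 and Krt5. The remaining 270 genes called in both went opposite ways, against 1199 for independent lists.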

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

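The tests of a changed cell composition and of exchanged labels or probe coverage, the test of a state of the cultures or RNA, and the splits within each Myc label were chosen only after the results they concern were seen.

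The change with the Rb- label differed between cells without and with the Myc+ label in 2715 genes by a test of the difference. Relative to all genes, the median difference was -0.383 for E2F targets, -0.447 for metabolic MYC targets, -0.552 for glycolysis, -1.1 for mesenchymal genes, -0.382 for proteases, -0.42 for TGF-beta targets, -0.106 for Wnt targets, 0.382 for interferon-induced genes, -0.474 for hypoxia-induced genes and -1.6 for fibroblast markers. These 10 lists passed with the preset correlation only, and 0 passed with an estimated correlation (adjusted p from 0.0519 to 0.345). The named genes whose change was higher with the Myc+ label were Efemp1 (5.28), Igfbp4 (3.89), Slco2a1 (3.83), Adgrg2 (3.83), Sbsn (3.40), Socs2 (3.22), Pcdh17 (3.22) and Nr1h5 (3.10). Those with a lower change were Mfap4 (-5.72), Slc43a3 (-5.30), Klhl13 (-4.58), Rarres2 (-3.81), Muc1 (-3.79), Lrrc32 (-3.54), Rpp25 (-3.43) and Thbs2 (-3.43). Socs2 and Adgrg2 lay at intensities of 29.68 and 6.385 in p53- Myc+ arrays and above 100 in the other groups. For Nr1h5 the difference comes from p53- arrays alone, at 123.3 against 5.621 or less in each other group. Among 13767 probe sets without a single gene name, which the comparisons did not use, 2126 were higher in p53- than in WT arrays and 432 lower, and 230 rose and 1539 fell with Rb loss without the Myc+ label.

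For each comparison of 3 against 3 arrays, the 10 splits are too few for a share under 0.05. The real split gave 5777 changed genes for p53 loss (1 split as large; highest other 1), 3949 for the Rb- label without the Myc+ label (1 split; highest other 0), 6640 for the Myc+ label without the Rb- label (1 split; highest other 0), 935 for the Rb- label with the Myc+ label (1 split; highest other 2) and 7246 for the Myc+ label with the Rb- label (1 split; highest other 0). The real numbers of lists in that order were 16, 10, 20, 8 and 20, with 14, 15, 17, 4 and 20 as the highest of the other splits and 1, 4, 1, 1 and 2 splits as large. For the difference of both changes with the Rb- label, 2 of 100 splits gave as many genes (2715; highest other 2842). These splits ignore the replicate numbers, and 1 other split gave more genes. Among 80 splits within each Myc label that part all 3 pairs of the arrays labelled Myc+, 1 gave as many genes (highest other 2137, the real groups with the Rb labels exchanged at 1 Myc label; 1024 among the rest). Both shares are under 0.05, so chance can be excluded only for a grouping of arrays without any effect. Such splits also remove the effects of the labels themselves, so they do not test whether the changes with the Rb- label differ, which rests on limma's test alone. For the 10 lists of the difference chance cannot be excluded, since 66 of 100 splits gave as many (highest other 21), and 9 of the 80 (highest other 12). In the Rb comparison with the Myc+ label, the replicate numbers were taken to pair the arrays. There 3 other splits also part all 3 pairs, and these gave 2, 0 and 0 genes and 0, 0 and 3 lists. The remaining 6 part 1 pair.

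The epithelial transcripts Krt18, Krt5 and Epcam lay near the bottom of the scale in the arrays labelled Myc+. Scaling as the cause is argued against, because 33 of 38 luminal genes still fell under the scaling that left fewest. A lower share of epithelial cells among otherwise unchanged cells would raise markers that only the other cells make. Of 20 fibroblast markers, 5 fell and 8 rose by 1 or more on the log2 scale from p53- to p53- Myc+ arrays. From p53- Rb- to p53- Rb- Myc+ arrays, 8 fell and 1 rose by as much. These values argue against a lower share only if epithelial cells do not make the markers, which was not measured. A different fibroblast-like population in these cultures may be present and cannot be told apart from a loss of epithelial identity within the cells: the lowest of Col1a1, Col1a2, Sparc and Vim had an intensity of 1056 in p53- Myc+ arrays, against a median of 56.5 over all genes, and either would give that. Whether MYC itself changed the cells' identity was not tested. The labels do not say whether the other cultures received a control virus, and Rb1 differed as well (161.5 in p53- and 36.43 in p53- Myc+ arrays).

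The mouse Myc probe set was lower in both groups labelled Myc+. Ribosome biogenesis genes known as MYC targets were higher in the arrays labelled Myc+ in both comparisons, with 0.0112 as the larger adjusted p of camera with an estimated correlation. That argues against exchanged Myc labels only if the groups do not also differ in cell population, which is open here. A probe set that reads the mouse transcript and not the transgene would show no rise. It would not by itself give the change of -2.73 on the log2 scale, which also needs a lower mouse transcript. The probe positions and the transgene's sequence are not analysed here. A lower mouse transcript beside an unread transgene therefore cannot be told apart from a lower total of Myc transcripts.

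Of the 3842 genes that rose with p53 loss, 1567 fell again with Rb loss without the Myc+ label, against 401.4 for independent lists, and the changes correlated at -0.652, against -0.499 for simulated unchanged groups that share the p53- arrays (covariance -0.151 against -0.0206, 20 simulations). Scaling as the whole cause is argued against: 871 of these genes (55.6%) still rose and fell after centring each array. Both groups of the second comparison carry the p53- label, so p53 loss by itself does not account for the fall of these genes. Of all 3842 risers, returned or not, 26.6% were also higher in p53- Rb- than in WT arrays. By the bounds set beforehand, that share decides nothing about the rise. A state of the cultures or RNA that also differs between arrays of 1 group is a candidate explanation: deviations from the group mean correlated across genes with the change from WT to p53- at 0.461 in p53- Rb- replicate 2 and -0.444 in p53- Rb- replicate 3, against -0.254 to 0.162 in the Myc+ arrays. The WT and p53- arrays enter that change themselves and are no independent reference. They lay at -0.0712 to 0.105 in WT, and the p53- arrays spread about as widely as the p53- Rb- arrays, at -0.369 in replicate 2 and 0.425 in replicate 3. Rb loss as the biological cause of the return stays open, since these arrays differ by the Rb- label too.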

How the results depend on the processing

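The constants added for the gene lists and the joint omission of p53- array 2 and p53- Rb- array 3 were chosen after the data were seen. Over all alternatives, values of named genes kept direction and side of the threshold in 10723 cases, lost the call in 122, gained it in 28 and reversed in 0. Results of the lists that passed or were selected for description did so in 2585, 128, 13 and 1. The cholesterol synthesis list of the Rb comparison with the Myc+ label is outside this tally. The reversed result was the interferon-induced list with the Rb- label without the Myc+ label, at 0.217 among genes above the median level. Array weights gave 8515 changed genes for the Rb- label without the Myc+ label and 5397 for the difference of both Rb changes. An estimated correlation left 7 lists for p53 loss, 3 and 0 for the Rb- label without and with the Myc+ label, 10 and 9 for the Myc+ label without and with the Rb- label, and 0 for the difference. Genes above the median level alone gave 4 lists for the Rb- label without the Myc+ label and 5 for the difference, and quantile normalization gave 6 and 6; the cause was not tested. Without 1 array at a time, changed genes numbered 3467 to 6094 for p53 loss, 2096 to 4724 for the Rb- label without and 647 to 1030 with the Myc+ label, 5646 to 6956 for the Myc+ label without and 5811 to 7633 with the Rb- label, and 1760 to 3233 for the difference; fewer arrays also lower the power. Lists numbered 15 to 17, 7 to 12, 6 to 9, 18 to 20, 20 to 20 and 9 to 11 in that order, and the correlations across genes -0.108 to 0.0559 for the Rb changes and 0.713 to 0.771 for the Myc+ label. Without p53- array 2 and p53- Rb- array 3 together, 6167, 2674, 1052, 6471, 6390 and 2193 genes changed.

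The labels do not say that replicate numbers pair arrays. Over 30 same-number pairs of all groups, deviations from the group mean correlated at -0.375 to 0.379, above 0.1 in 11 pairs, and the own number correlated best in 12. Outside the Rb comparison with the Myc+ label, where the numbers were taken to pair the arrays, at most 2 of 3 pairs of a comparison lay above 0.1. With the numbers as a replicate block, 5899 genes changed for p53 loss, 4010 and 930 for the Rb- label without and with the Myc+ label, 6697 and 7344 for the Myc+ label without and with the Rb- label, and 2777 for the difference. In the Rb comparison with the Myc+ label the block gave 9 lists in place of 8, ended 38 calls of genes and added 33. Apart from the cholesterol synthesis list and Rb1 it changed no call of a list or a named gene there. Changes of genes near the bottom of the scale depend on the added constant, and the median of all intensities was 47.32.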

Other observations

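Set against WT, counts that were computed only after the comparisons had been seen, S-phase genes known as E2F targets were higher in 24 of 46 in p53-, 35 in p53- Rb-, 42 in p53- Myc+ and 44 in p53- Rb- Myc+ arrays, and mitosis genes in 33, 35, 37 and 37 of 38. DNA repair genes were higher in 19, 15, 23 and 24 of 25. Targets of p53 were lower in 16, 13, 26 and 24 of 35. Lower in all 4 groups without p53 were 11 of them: Mdm2, Ccng1, Zmat3, Phlda3, Aen, Eda2r, Rps27l, Btg2, Ddit4, Dcxr and Psrc1. All these counts share the WT arrays, and their differences between groups were not tested. As all 4 groups carry the p53- label, the counts of p53 targets do not grade the loss of p53.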
